A study of Arabidopsis thaliana with 4 samples.

How the data were processed

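RNA from inflorescence apices of the mutant rtr-2 and of wild type (ecotype Col) was compared on 4 arrays of 1 Agilent design with 60-base probes. Per the labels, seeds were cold-treated for 2 days at 4 °C, apices of 11 plants per genotype were collected in each of 12 experiments, and each pool joined 3 experiments. Per the labels, RNA was extracted with Trizol, 1 µg was amplified, and 5 µg of the amplified RNA was labelled with Cy3 or with Hype5, which is read in the Cy5 channel. All arrays share 1 slide and 1 scan, so neither is a batch. Pools came from separate plants, so the p-values measure a spread between pools together with that of labelling and hybridisation. Only differences between arrays of the same dye orientation enter that spread, as the dye term takes up those it cannot tell from dye.

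The deposited scanner files hold, per the file headers, spot intensity values made with Agilent Feature Extraction 10.7.3.1: the mean and local background intensity in green (Cy3) and red (Cy5), processed intensity (background-subtracted, detrended and dye-normalized by that software), and a log10 ratio of red over green processed signals. The deposited value table of the same arrays holds 1 value per spot whose scale and direction were found from the values: it is a log2 ratio of rtr-2 over wild type, centred on a mean of 0, with column medians of -0.02, 0.03, -0.01 and 0. It correlated at 0.852 to 0.874 with each array's own log10 ratio turned the same way, and its slope on the log2 ratios computed here was 0.956 to 1.057. How the authors normalized that table is not given in the sources used here, and it served only as an alternative.

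Intensities were background-corrected with normexp (offset 50) and normalized within arrays by loess in limma 3.58.1 under R 4.3.3, with control spots at weight 0. Control spots and spots that the software marked as outliers were left out (120 to 473 spots per array), spots of a probe were averaged, and no scaling between arrays was applied. A probe was tested where it was well above background on at least 3 of the 4 arrays in the channel of at least 1 genotype. Of 43603 probes, 36309 were assigned to a locus through the accessions and names in the files and the RefSeq gene table of assembly TAIR10.1, and symbols were updated from that table. A gene with several tested probes was represented by the brightest, and probes with no locus were kept as features of their own, which gave 21600 genes and 3441 such probes. Among 6512 genes with several tested probes, 3 had changed probes that moved in opposite directions. Probe coordinates are those in the files, and no genome sequence was used.

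The design was fixed before the data were examined. limma's lmFit and eBayes were run on the red over green log2 ratios with a dye column and a genotype column (+1 where rtr-2 was in Cy5 and -1 where it was in Cy3), with Benjamini-Hochberg adjustment and a threshold of 0.05; the residual degrees of freedom were 2 and the prior added 3.45. The sign was set from the dyes in the labels. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation and with fry, adjusted over 22 lists. These tests take the members with values on all 4 arrays. With an estimated correlation camera takes only the residual degrees of freedom, so a small p is hard to reach and not passing decides little. Of 390 list members fixed in advance, 7 were left out because the locus did not carry the listed symbol, and 373 were tested. The genes named are, by a rule fixed in advance, the 8 with a locus that rose most and the 8 that fell most among those past the threshold with the same direction on all 4 arrays, up to 4 members with the smallest adjusted p of each list that passed camera or had at least 3 changed members, and TFL1, LFY, AP1, FT, SOC1, WUS, STM and AG. Further list members are named where a group that rose, fell or did not pass had at most 5, where a member was dim in rtr-2, or for the young flower, and the text says that these were chosen after their values were seen. Of the changed features, 119 were not well above background on any array in rtr-2 and 13 on any in wild type, so that their ratios are only bounds. For list members of this kind the bound compares, after loess and Aquantile, the bright genotype's mean with the mean over arrays of the higher of the lowest signal well above background and the probe's own.

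The fit was tested on simulated data made from the real dye effects and residual spreads of 24431 features, with 200 changed by known amounts in rtr-2 against wild type. It recovered 92% of features changed by 3 on the log2 scale, 88% by 2, 38% by 1 and 0% by 0.5, with 2 of 24231 unchanged features called. With few changed features the adjusted threshold is strict, so these shares are not those of the real comparison. Alternatives tried were no background subtraction, the processed signals, median centring, Aquantile scaling, no filter and a strict brightness filter (both channels well above background on all 4 arrays), no dye column, eBayes with trend and robust options, array weights, the mean of a gene's probes, every probe on its own, the authors' value table, and each array left out. One further alternative, the changed features with the same direction on every array, was added after the data were seen. Green negative control spots had median signals of 347.3 to 369.6 against a local background of 113 to 126, so that local background alone leaves signal in dim green spots.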

Results

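Transcript levels were compared between inflorescence apices of the Arabidopsis thaliana mutant rtr-2 and of its wild type, ecotype Col, on 4 two-colour oligonucleotide arrays. Apices came from plants grown for 32 days with 14 h of light and 10 h of dark, whose bolts were shorter than 1 cm. Each array set 1 rtr-2 pool against 1 wild-type pool, and a pool held 33 plants of a genotype from 3 independent experiments, so that the 4 array ratios are the replicates (n = 4). rtr-2 carried Cy3 on replicates 1 and 3 and Cy5 on replicates 2 and 4. The gene altered in rtr-2 is not given in the sources used here, so its own transcript could not be examined. Between 67.1% and 75.7% of the spots were well above background in the green (Cy3) channel and between 84.8% and 87.8% in the red (Cy5) channel, with median signals of 878 to 1007.9 in green and 512.1 to 572.9 in red, and no spot was saturated. Values below are log2 ratios of rtr-2 over wild type ± the standard error (SE) of the limma fit, and the number of arrays limits their precision.

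The first question was which transcripts differed in rtr-2 apices. Of the 8 largest falls 3 were in genes of the tapetum and pollen list, and the largest rises, of up to 12.1-fold, included a cell wall enzyme and transcription factors of the AP2 and WRKY families. Of 25041 features tested, 6169 (24.6%) differed at an adjusted p under 0.05, 3195 higher and 2974 lower. Which direction held more features depended on the setting, with 3118 higher and 3400 lower after median centring, 3519 and 3693 in the authors' value table and 1744 and 1771 without replicate 4. A difference of at least 2-fold was seen for 1482 features, 834 higher and 648 lower, and for 2531 with the scanner software's processed signals. At 8-fold or more the balance was uneven, with 11 features higher and 113 lower. The fit gives gene-specific dye differences a term of their own, and without it 1282 features passed. Leaving out 1 array gave 2484 features without replicate 2, 3515 without replicate 4 and 4019 without replicate 3. The residual then comes only from the pair of arrays in the other dye orientation. A call lost this way, here and below, can reflect a gap within that pair rather than the array left out.

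The 8 largest falls among genes that moved the same way on all 4 arrays were in genes well above background in wild type on all 4 arrays and in rtr-2 on 2 or 3 of them. AT5G44540, described on the array as related to a tapetum-specific protein, fell by 7.57 ± 0.14 (adjusted p = 9.68e-05), with rtr-2 well above background on 2 of 4 arrays and array values from -8.885 to -6.11; the dye term takes up most of that spread and the SE does not include it. LTP12, a lipid transfer protein of the tapetum, the nutritive cell layer of the anther, fell by 6.21 ± 0.09. CYP704B1, a fatty acid hydroxylase needed for the pollen wall, fell by 6.36 ± 0.21, and LAP5, a polyketide synthase of the same pathway, stood at -5.91 ± 0.22. The other 4 were the lipase-like gene AT1G20130 at -6.31 ± 0.26, the lipid transfer genes AT1G66850 at -6.26 ± 0.19 and AT5G62080 at -5.93 ± 0.26, and the peroxidase gene AT1G44970 at -6.13 ± 0.16. The sizes of these falls depended on the processing and are given without folds, with AT5G44540 at -9.19, CYP704B1 at -8.21 and AT1G20130 at -8.38 with the processed signals, against -6.75, -5.74 and -5.69 without background subtraction, and AT1G20130 at -4.07 as the mean of its probes. All 8 passed under each of the 14 alternatives that gave them a value. On the build ath1:Jan2004 of the file headers, the probe of AT5G44540 lies on chromosome 5 from 17941303 to 17941362.

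The largest rises were smaller. AT5G52760, which encodes a protein with a heavy-metal-associated domain, rose by 3.59 ± 0.19, a 12.1-fold difference (adjusted p = 0.000552), and its probe lies on chromosome 5 from 21387484 to 21387543. XTH18, a xyloglucan endotransglucosylase/hydrolase of the cell wall, rose by 3.58 ± 0.28, with its probe on chromosome 4 from 14825946 to 14826005. AT1G77640, an AP2-domain transcription factor, rose by 3.35 ± 0.11, and the transcription factor WRKY57 by 3.17 ± 0.12. The receptor gene AT2G20142 rose by 3.26 ± 0.15 (2.18 as the mean of its probes), the starch-related gene QQS by 3.24 ± 0.14, the oxidoreductase gene AT5G37940 by 3.09 ± 0.17 and AT5G50335, of unknown function, by 3.08 ± 0.14.

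**Figure D1:**
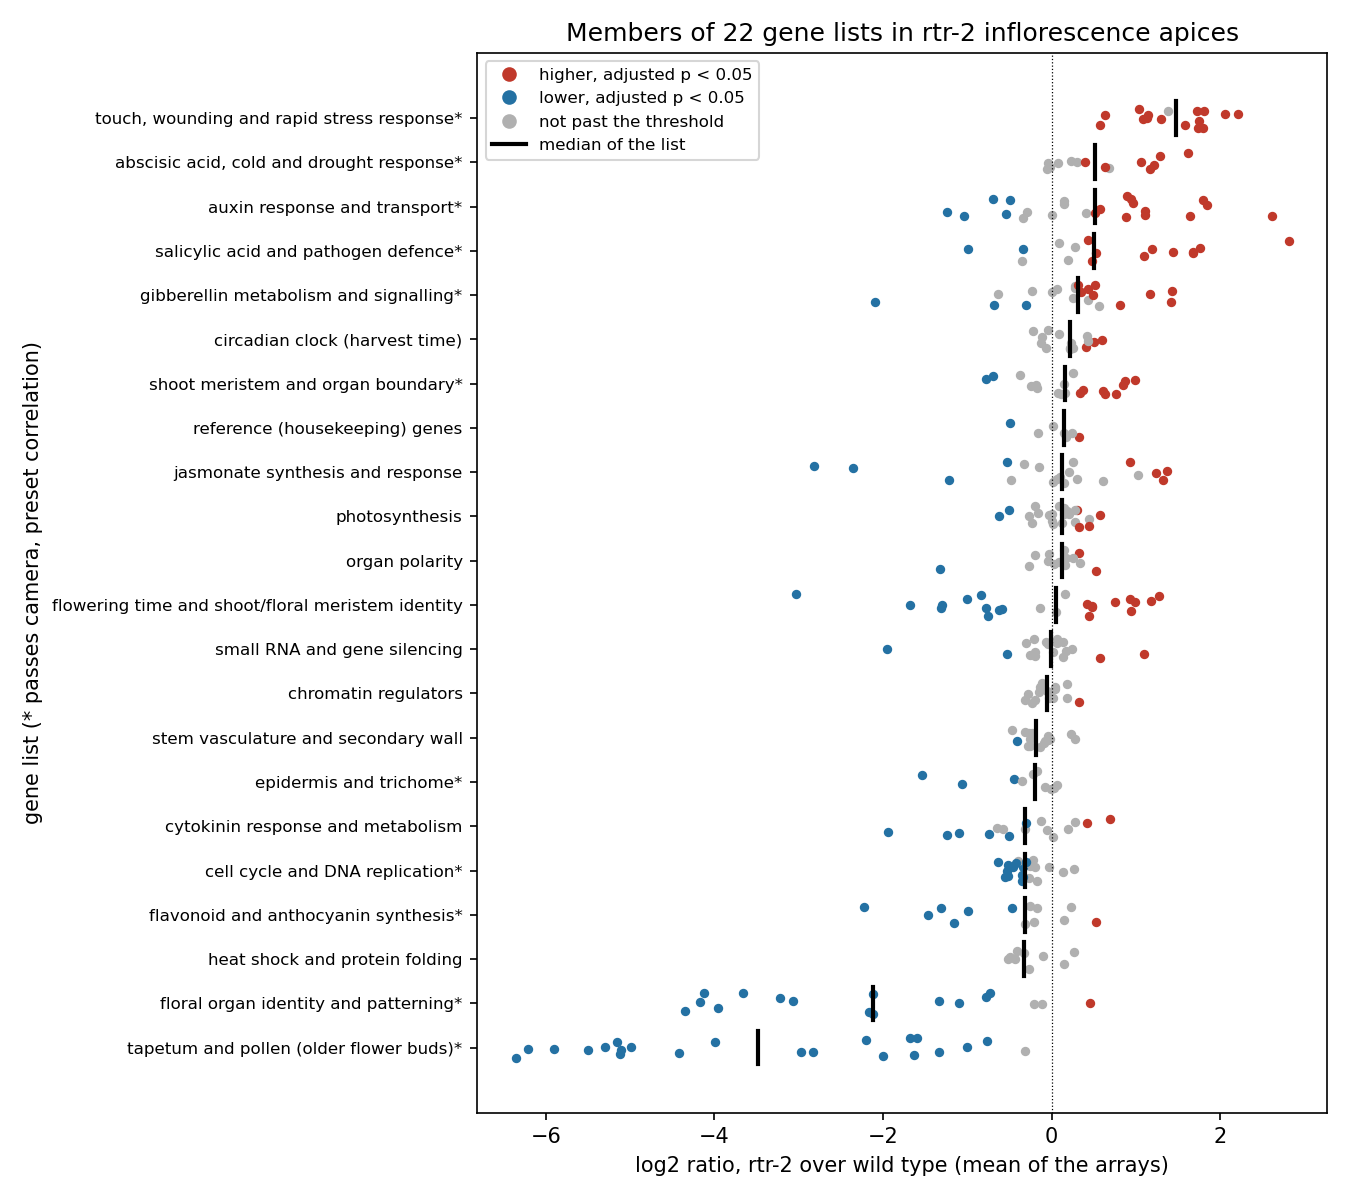
Log2 ratio of rtr-2 over wild type (horizontal axis) for every tested member of the 22 gene lists (vertical axis, in order of their medians), where points are genes, red if higher and blue if lower at an adjusted p under 0.05 and grey otherwise, black bars are list medians, and an asterisk marks a list that passed camera with the preset correlation. The tapetum and pollen list lies lowest, with a median of -3.48, and the touch, wounding and rapid stress list highest, with a median of 1.48.

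The second question was which groups of genes moved together, tested on 22 lists fixed in advance. Tapetum and pollen genes, markers of older flower buds, fell as a group. Of 22 members tested, 21 fell and 0 rose, also adjusted over the list alone, with a median of -3.48 (camera adjusted p = 3.65e-17, and adjusted p = 0.422 with an estimated correlation). The median was -5.08 with the processed signals and -2.01 for the 5 members left by the strict brightness filter. That filter leaves out members that are dim in rtr-2, from CYP704B1 at -6.36 to CALS5 at -0.77, so its median is of a selected set. ACOS5 and MS2, enzymes that make pollen wall precursors, stood at -5.50 ± 0.13 and -5.15 ± 0.17, each with rtr-2 well above background on 2 of 4 arrays. MS1 and MYB80, regulators of tapetum development, were not well above background on any array in rtr-2 and were at least 2.88-fold and at least 2.46-fold lower. With both at these bounds the list median is -3.48 as before, since either way both lie above it. These bounds hold only for the processing used here. Without background subtraction MS1 stood at -1.102 and MYB80 at -0.88, and with the processed signals at -4.62 and -4.11. With no background subtraction and signals raised to a level that few probes not well above background exceed, they stood at -0.876 and -0.718. The falls without background subtraction were thus smaller than the bounds. ACOS5 ran from -7.80 with the processed signals to -4.89 without background subtraction, and MS2 from -7.36 to -4.59. The member that did not pass was TPD1, at -0.32 ± 0.17. MS1, MYB80 and TPD1 were chosen after their values were seen.

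Floral organ identity genes also fell. Of 17 members, 14 fell and 1 rose, also adjusted over the list alone, with a median of -2.12 (camera adjusted p = 1.47e-09, and adjusted p = 0.422 with an estimated correlation). The size of the median depended on the setting, from -3.57 with the processed signals to -1.095 for the 11 members left by the strict brightness filter. That filter leaves out members that are dim in rtr-2, from SEP2 at -3.96 to SUP at -1.33, so its median is of a selected set. SEP3 and SEP1, MADS-box factors that act in all floral organs, stood at -4.36 ± 0.19 (20.5-fold lower) and -4.17 ± 0.17 (18.1-fold lower). PI, which specifies petals and stamens, fell by 4.13 ± 0.16, and AG, which specifies stamens and carpels, fell by 3.22 ± 0.18. CRC, a carpel and nectary factor, fell by 2.12 ± 0.08. Processed signals gave lower values for SEP1 (-4.92, against -3.48 as the mean of its probes), AG (-4.195) and CRC (-2.75), and AG and CRC stood at -2.72 and -1.725 without background subtraction. Chosen after their values were seen, NUB, a zinc finger gene of organ growth, rose by 0.46 ± 0.08, a call lost without replicate 2 (adjusted p = 0.0768) or 4 (0.0534) or the dye term (0.329), and AP2 and JAG, at -0.11 and -0.21, did not pass.

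Flowering time and meristem identity genes moved in both directions. Of 23 members tested, 10 rose and 10 fell, also adjusted over the list alone, and the list did not pass camera (adjusted p = 0.889). Its median of 0.06 and its mean of -0.17 differed in sign, and camera's direction was down. AP1, which confers floral identity on young meristems, fell by 3.04 ± 0.15 (8.2-fold, adjusted p = 0.000454). SPL5, SPL3 and SPL15, which promote the floral transition, were 3.21-fold, 2.49-fold and 2.47-fold lower. LFY, the other main floral identity gene, was at 0.06 ± 0.19 (adjusted p = 0.846) and was higher on 2 of 4 arrays. TFL1, which keeps the shoot meristem from turning floral, rose by 0.99 ± 0.18 and was higher on 3 of 4 arrays (adjusted p = 0.0174), a call lost without replicate 2 (0.103) or 4 (0.0636). SOC1, a promoter of flowering, rose by 0.42 ± 0.08 (adjusted p = 0.0161), lost without replicate 1 (0.0511), 2 (0.0712) or 4 (0.0766). The calls of TFL1 (0.224), SOC1 (0.133) and SPL15 (0.05) were also lost without the dye term. FT was not tested because its probes were too dim, and the flowering repressors FLC and FLM, chosen after their values were seen, did not pass, at -0.14 and 0.16. AGL14, a MADS-box gene also chosen after its value was seen, was not well above background on any array in rtr-2 and was at least 1.32-fold lower, stood at -0.42 without background subtraction and at -2.55 with the processed signals, and was lost without the dye term (0.0881), and with it at the bound the list median is 0.06.

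**Figure D2:**
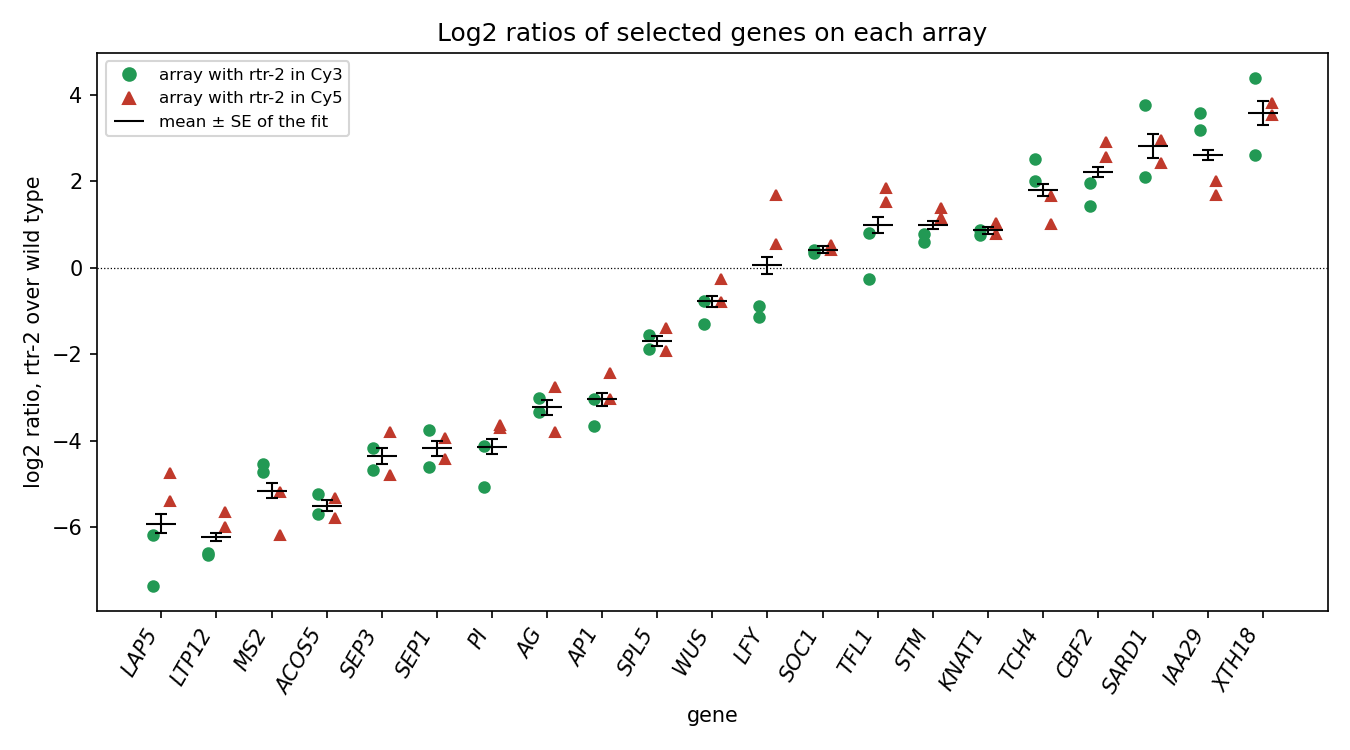
Log2 ratio of rtr-2 over wild type (vertical axis) on each of the 4 arrays for 21 genes (horizontal axis), where green circles are arrays with rtr-2 in Cy3, red triangles arrays with rtr-2 in Cy5, and black bars the mean ± SE of the fit. The genes from LAP5 to WUS lie below 0 on all 4 arrays, and LFY lies below 0 with rtr-2 in Cy3 and above 0 with rtr-2 in Cy5.

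Among shoot meristem and boundary genes more rose than fell. Of 19 members, 8 rose, 2 fell and 9 did not pass, and adjusted over the list alone 9 rose and 4 fell, with a median of 0.15 (camera adjusted p = 0.0427, and adjusted p = 0.603 with an estimated correlation). STM, required to maintain the meristem, rose by 0.99 ± 0.09, and the related homeobox genes KNAT1, KNAT6 and KNAT2 rose by 0.87 ± 0.09, 0.85 ± 0.10 and 0.76 ± 0.08. WUS, which maintains stem cells, fell by 0.77 ± 0.13 (adjusted p = 0.0138), lost without replicate 2 (0.0746), and AS2, a leaf development gene chosen after its value was seen, fell by 0.69 ± 0.08. The calls of KNAT6 (0.0861), KNAT2 (0.101), WUS (0.0958) and AS2 (0.137) were lost without the dye term, and AS2 stood at -0.46 as the mean of its probes. The list's call was also lost with the scanner software's processed signals (0.0535), without the dye term (0.0657), with the strict brightness filter (0.0935) and without replicate 1 (0.105) or 2 (0.138). The tapetum and pollen markers stood at a median of -3.48 in the same RNA.

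Touch, wounding and rapid stress genes rose together. Of 16 members, 15 rose and 0 fell, also adjusted over the list alone, with a median of 1.48. The camera adjusted p was 1.47e-09, and 0.422 with an estimated correlation. That correlation was estimated at 0.428, so the p at the preset 0.01 is too small if the estimate holds. CBF2, a regulator of the cold response, rose by 2.22 ± 0.12 (4.65-fold), TCH4, a touch-induced wall enzyme, by 1.80 ± 0.15, TCH2, a calmodulin-like protein, by 1.15 ± 0.08, and ERF5, an ethylene response factor, by 1.08 ± 0.09. TCH2 stood at 2.08 and 2.33 with rtr-2 in Cy3 but at 0.105 and 0.078 with rtr-2 in Cy5, and without the dye term its call (adjusted p = 0.275) and that of ERF5 (0.0673) were lost. WRKY18, chosen after its value was seen, stood at 1.38 ± 0.72 on 3 arrays and did not pass (adjusted p = 0.23). The tapetum and pollen median was -3.48 in these pools.

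Salicylic acid and pathogen defence genes rose on balance, with 10 of 16 members higher and 2 lower, also adjusted over the list alone, and a median of 0.50 (camera adjusted p = 0.000951, and adjusted p = 0.422 with an estimated correlation). The median was 0.355 with no filter on dim probes and 0.83 with the processed signals. SARD1, a regulator of salicylic acid synthesis, rose by 2.82 ± 0.27 (7.04-fold), the transcription factor WRKY38 by 1.76 ± 0.15 and PAD4, a lipase-like defence regulator, by 1.44 ± 0.12, and WRKY54 was 2.14-fold higher. WRKY38 stood at 1.33 without background subtraction and at 2.78 with the processed signals. Members chosen after their values were seen were PBS3, which fell by 0.996 ± 0.10, PR5, which fell by 0.34 ± 0.09 and was lost on leaving out any 1 array (adjusted p from 0.0608 without replicate 1 to 0.178 without replicate 2), with the processed signals (0.0646), as the mean of its probes (0.0675) and without the dye term (0.278), and SID2, AIG1, ACD6 and NIMIN1, which did not pass. AIG1 passed with the processed signals (0.0205) and NIMIN1 without replicate 4 (0.0453). In the same RNA the medians of the bud markers were -3.48 for tapetum and pollen and -2.12 for floral organs.

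Of 14 abscisic acid, cold and drought genes, 7 rose and 0 fell, also adjusted over the list alone, with a median of 0.52 (camera adjusted p = 0.00212, and adjusted p = 0.422 with an estimated correlation). P5CS1, an enzyme of proline synthesis, rose by 1.22 ± 0.09 and ABI1, a phosphatase of abscisic acid signalling, by 1.06 ± 0.09. NCED3, an enzyme of abscisic acid synthesis, rose by 1.62 ± 0.32, lost without replicate 2 (adjusted p = 0.115) or 4 (0.0702). The dehydrin gene ERD10 rose by 1.29 ± 0.29, lost without replicate 2 (0.133) or 4 (0.113), with the processed signals (0.054) and with eBayes trend and robust options (0.0534). Without the dye term the calls of ABI1 (0.122), NCED3 (0.0718) and ERD10 (0.0798) were lost, and ABI1 stood at 1.77 and 1.61 with rtr-2 in Cy3 against 0.327 and 0.542 in Cy5. With the processed signals NCED3 stood at 2.33, and without replicate 3 ERD10 stood at 0.83. Bud markers fell in the same pools, tapetum and pollen genes to a median of -3.48 and floral organ genes to -2.12.

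Jasmonate genes moved both ways, with 4 of 20 members higher and 4 lower, also adjusted over the list alone. The vegetative storage protein genes VSP1 and VSP2, often used as jasmonate markers, stood at -2.82 ± 0.23 and -2.36 ± 0.27, and LOX2, a lipoxygenase of jasmonate synthesis, fell by 1.22 ± 0.12. MYC2, a transcription factor of the pathway, rose by 0.94 ± 0.17, lost without replicate 2 (adjusted p = 0.0913) or 4 (0.066). The repressor genes JAZ1, JAZ7 and JAZ8 rose by 1.32 ± 0.25, 1.37 ± 0.27 and 1.23 ± 0.33 and JAZ9 fell by 0.53 ± 0.13. These JAZ genes were chosen after their values were seen, and their calls were lost without replicate 2 (0.0887, 0.101, 0.141 and 0.184) or 4 (0.0885, 0.0916, 0.176 and 0.0817), JAZ9 also without replicate 1 (0.0998). The dye term's removal ended the calls of VSP2 (0.0742), LOX2 (0.13), MYC2 (0.0838), JAZ1 (0.0562), JAZ7 (0.113), JAZ8 (0.181) and JAZ9 (0.161), and the processed signals those of JAZ8 (0.0754) and JAZ9 (0.0745). JAZ8 was also lost with eBayes trend and robust options (0.078) and with no filter (0.0535), and VSP2 stood at -1.68 as the mean of its probes. JAZ8 stood at 0.725 without replicate 3. Without replicate 2 or 4 the residual is the gap between replicates 1 and 3, where JAZ8 stood at 0.748 and 2.782. The list did not pass camera (adjusted p = 0.775), but passed as higher without replicate 1 (0.0174, median 0.50). Its median of 0.13 and mean of -0.015 differed in sign, as did the directions of camera (up) and fry (down).

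Auxin genes rose on balance, with 12 of 23 members higher and 5 lower, or 13 and 6 adjusted over the list alone, and a median of 0.52 (camera adjusted p = 0.0075, and adjusted p = 0.447 with an estimated correlation). The auxin-induced repressors IAA29 and IAA7 rose by 2.62 ± 0.11 (6.13-fold) and 1.64 ± 0.14, and GH3.5 and DFL1, enzymes that conjugate auxin to amino acids, by 1.85 ± 0.12 and 1.80 ± 0.10. The 5 that fell, chosen after their values were seen, were the auxin synthesis genes YUC1 at -0.49, YUC4 at -0.70 and TAA1 at -0.55, the last lower on 2 of 4 arrays, and the conjugating enzyme genes GH3.2 at -1.04 and GH3.3 at -1.24. Calls were lost without replicate 2 for GH3.3 (adjusted p = 0.181), YUC4 (0.0561) and TAA1 (0.0511), and without replicate 4 for GH3.3 (0.0982) and YUC1 (0.0649). None of these 5 passed without the dye term (YUC4 0.051, GH3.2 0.11, GH3.3 0.117, YUC1 0.259 and TAA1 0.401), and GH3.3 (0.0646) and YUC1 (0.0524) were lost with the processed signals, GH3.3 also with eBayes trend and robust options (0.0696). Without replicate 1 GH3.3 stood at -0.78. Beside this, the tapetum and pollen median was -3.48 and the floral organ median -2.12 in the same RNA.

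Of 21 gibberellin genes, 9 rose and 3 fell, or 10 and 3 adjusted over the list alone, with a median of 0.31 (camera adjusted p = 0.0235, and adjusted p = 0.422 with an estimated correlation). GA2OX2 and GA2OX4, which inactivate gibberellins, rose by 1.43 ± 0.14 and 1.42 ± 0.12, and GASA4, a gibberellin-regulated gene, by 1.17 ± 0.13. RGL2, a repressor of gibberellin responses, was 4.29-fold lower. Chosen after their values were seen, its relative RGL1 fell by 0.68 ± 0.09 and GA2OX8 fell by 0.31 ± 0.07 but was lower on 2 of 4 arrays and was lost on leaving out any 1 array (0.0959 without replicate 1 to 0.146 without replicate 2). GA2OX8 was also lost under 6 other alternatives, 5 with the dye term kept (adjusted p from 0.0582 to 0.172) and 1 without it (0.657), and RGL1 without the dye term (0.0654). GA2OX4 stood at 1.02 without background subtraction and at 2.73 with the processed signals, and GA2OX8 at -0.18 and -0.54. The strict brightness filter ended the list's call (0.155). The same RNA had medians of -3.48 for tapetum and pollen genes and -2.12 for floral organ genes.

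Of 16 cytokinin genes, 2 rose and 6 fell, or 3 and 6 adjusted over the list alone, and the list did not pass camera (adjusted p = 0.0748). The cytokinin oxidase genes CKX3 and CKX5 stood at -1.94 ± 0.13 and -1.24 ± 0.09 and the response regulator gene ARR15 at -1.09 ± 0.14. ARR5 rose by 0.70 ± 0.10, lost without replicate 2 (0.0507) or 4 (0.052), and the synthesis gene IPT7, chosen after its value was seen, by 0.42 ± 0.10, lost without replicate 2 (0.162), 3 (0.128) or 4 (0.118) and without background subtraction (0.131). Without the dye term CKX5 (0.0513), ARR5 (0.218) and IPT7 (0.185) did not pass. Without background subtraction CKX3 stood at -1.575 and IPT7 at 0.19, and with the processed signals at -2.73 and 1.17. The list passed as lower with the strict brightness filter (0.0262), with no filter (0.047), without the dye term (0.0405), without replicate 3 (0.0279) and in fry (0.0492).

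Of 24 cell cycle genes, 12 fell, 0 rose and 12 did not pass, and 17 fell and 0 rose adjusted over the list alone, with a median of -0.32 (camera adjusted p = 6.8e-05, and adjusted p = 0.422 with an estimated correlation). The cyclin gene CYCA1;1 stood at -0.56 ± 0.08, lost without replicate 2 (adjusted p = 0.0511), and the cytokinesis kinesin gene HIK at -0.63 ± 0.10, lost without replicate 4 (0.0513). The ribonucleotide reductase gene TSO2 stood at -0.51 ± 0.09, lost without replicate 4 (0.0619). The cyclin gene CYCB1;2 stood at -0.46 ± 0.08 but was lower on 2 of 4 arrays and was lost without replicate 1 (0.0501), 2 (0.0577) or 4 (0.0769). None of these 4 passed without the dye term (CYCA1;1 0.0673, HIK 0.0838, TSO2 0.245 and CYCB1;2 0.487). In the same RNA the tapetum and pollen median was -3.48 and the floral organ median -2.12.

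Flavonoid genes were lower on balance, with 6 of 13 members lower and 1 higher, or 7 and 1 adjusted over the list alone, and a median of -0.32, or -0.21 without background subtraction (camera adjusted p = 0.00865, and adjusted p = 0.459 with an estimated correlation). FLS1, a flavonol synthase, fell by 2.23 ± 0.09 (4.68-fold), and the pathway genes TT7, CHS and F3H stood at -1.31 ± 0.13, -1.16 ± 0.08 and -0.99 ± 0.09. PAP1, an activator of anthocyanin synthesis chosen after its value was seen, rose by 0.52 ± 0.09, lost without replicate 2 (0.0772) or 3 (0.0507) or the dye term (0.163). The bud markers fell in the same RNA, with medians of -3.48 for tapetum and pollen and -2.12 for floral organs. Without replicate 4 the list's call was lost (0.0876).

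Of 10 epidermis and trichome genes, 3 fell and 0 rose, or 4 and 0 adjusted over the list alone, with a median of -0.20 (camera adjusted p = 0.0374, and adjusted p = 0.422 with an estimated correlation). The trichome regulators TRY and GL1 stood at -1.53 ± 0.13 and -1.06 ± 0.08, and GL3 at -0.44 ± 0.09, lost without replicate 2 (adjusted p = 0.0642), 3 (0.0905) or 4 (0.106). GL1 (0.0953) and GL3 (0.144) did not pass without the dye term, and GL3 stood at -0.32 without background subtraction and at -1.07 with the processed signals. ETC1, at -0.35 ± 0.10, did not pass (0.06), but did with median centring (0.0389) and with eBayes trend and robust options (0.0455). The list's call was lost with the processed signals (0.0818), the mean of a gene's probes (0.0522), the strict brightness filter (0.069) and without replicate 1 (0.0667) or 4 (0.0956). Tapetum and pollen genes (median -3.48) and floral organ genes (-2.12) fell in the same RNA.

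The other lists did not pass camera. Of 18 small RNA genes 2 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.831 for the list). AGO5, an Argonaute gene, fell by 1.96 ± 0.08 and the Dicer gene DCL3 stood at -0.53 ± 0.08. AGO3 was 2.14-fold higher, with wild type well above background on 2 of 4 arrays, and RDR1 rose by 0.58 ± 0.08, lost without replicate 2 (0.0515). RDR1 (0.0718) and DCL3 (0.163) did not pass without the dye term, and AGO3 stood at 0.67 without background subtraction and at 2.62 with the processed signals. Of 14 organ polarity genes 2 rose and 1 fell, or 3 and 2 adjusted over the list alone (list 0.412). INO, a factor of the ovule's outer integument, fell by 1.32 ± 0.18, with rtr-2 well above background on 2 of 4 arrays, and its value ran from -2.97 with the processed signals to -0.91 over the alternatives. ATHB15 rose by 0.53 ± 0.09, lost without replicate 2 (0.0731) or 4 (0.0693) and with the processed signals (0.054), and YAB5 by 0.32 ± 0.08, lost on leaving out any 1 array (0.0799 without replicate 1 to 0.126 without replicate 2), and neither passed without the dye term (0.215 and 0.325). YAB3 stood at -0.27 ± 0.08 (0.0533) and passed under 4 alternatives, among them the authors' value table (0.0461).

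Of 15 circadian clock genes, kept as a check of harvest time, 3 rose and 0 fell, also adjusted over the list alone (list adjusted p = 0.0748). These were RVE1 at 0.60 ± 0.10, PRR9 at 0.50 ± 0.10, which was higher on 3 of 4 arrays and was lost without replicate 1 (0.069) or 2 (0.116), and TOC1 at 0.41 ± 0.09, lost on leaving out any 1 array (0.0535 without replicate 1 to 0.14 without replicate 2) and with the processed signals (0.107). GI stood at 0.25 ± 0.08 (0.0838). Without the dye term RVE1 (0.0858), PRR9 (0.329) and TOC1 (0.264) did not pass. The list passed as higher with no filter on dim probes (0.0431) and without replicate 3 (0.00647).

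Of 23 photosynthesis genes 4 rose and 2 fell, also adjusted over the list alone (list adjusted p = 0.415). The light-harvesting gene LHCB1.3 rose by 0.58 ± 0.12 on its 3 arrays, lost with the processed signals (0.0601), and LHCB2.2 rose by 0.30 ± 0.08 but was higher on 2 of 4 arrays and was lost on leaving out any 1 array (0.0802 without replicate 1 to 0.156 without replicate 3). The Rubisco small subunit gene RBCS3B stood at -0.62 ± 0.14, lost without replicate 1 (0.0586), 2 (0.0735) or 3 (0.068). RBCS2B stood at -0.51 ± 0.08 but was lower on 2 of 4 arrays, its probe also lists transcripts of another locus, the call was lost without replicate 2 (0.059) or 4 (0.0574), and the value turned to 0.08 with the processed signals. LHCA4 and PSBO2, chosen after their values were seen, rose by 0.44 ± 0.11 and 0.33 ± 0.09, and both calls were lost without replicate 1 (0.101 and 0.0974), 3 (0.103 and 0.14) or 4 (0.129 and 0.0763), PSBO2 also without replicate 2 (0.183). None of these 6 passed without the dye term (0.12 for RBCS3B to 0.777 for LHCB2.2). Other settings ended the calls of LHCB2.2 (0.0527 in the authors' value table, 0.0788 with the processed signals and 0.173 with median centring, where it stood at 0.20) and of PSBO2 (0.0543 as the mean of its probes to 0.182 with median centring).

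Of 9 heat shock genes 0 rose and 0 fell in limma, over all genes and adjusted over the list alone (list adjusted p = 0.426), and without replicate 3 this list passed as lower (0.000173, median -0.74). Of 16 stem vasculature genes 0 rose and 1 fell, FLA11 at -0.42 ± 0.09, and 0 adjusted over the list alone (list 0.121). Of 17 chromatin regulators 1 rose, the methyltransferase gene DRM2 at 0.32 ± 0.08 on 3 of 4 arrays, and 0 adjusted over the list alone (list 0.747), though fry gave 0.0382 in the downward direction. Of 7 reference genes ACT2 rose by 0.33 ± 0.08, higher on 3 of 4 arrays, and GAPC1 stood at -0.49 ± 0.08, with 1 each way adjusted over the list alone (list 0.763). ACT7, ACT8, UBQ10, PP2AA3 and UBC21 did not pass, at -0.16 to 0.24. The 9 genes named here were chosen after their values were seen. Calls of DRM2 (0.0642 to 0.168) and ACT2 (0.0601 to 0.143) were lost on leaving out any 1 array, lowest for replicate 1, and with median centring (0.067 and 0.115). Those of FLA11 were lost without replicate 2 (0.0974), 3 (0.104) or 4 (0.119) and of GAPC1 without replicate 2 (0.0731) or 4 (0.06) and as the mean of its probes (0.0526, with GAPC1 at -0.30). The processed signals ended the calls of DRM2 (0.106) and ACT2 (0.0893), and these and the other 2 calls were lost without the dye term (GAPC1 0.283, FLA11 0.344, DRM2 0.396 and ACT2 0.452).

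**Figure D3:**
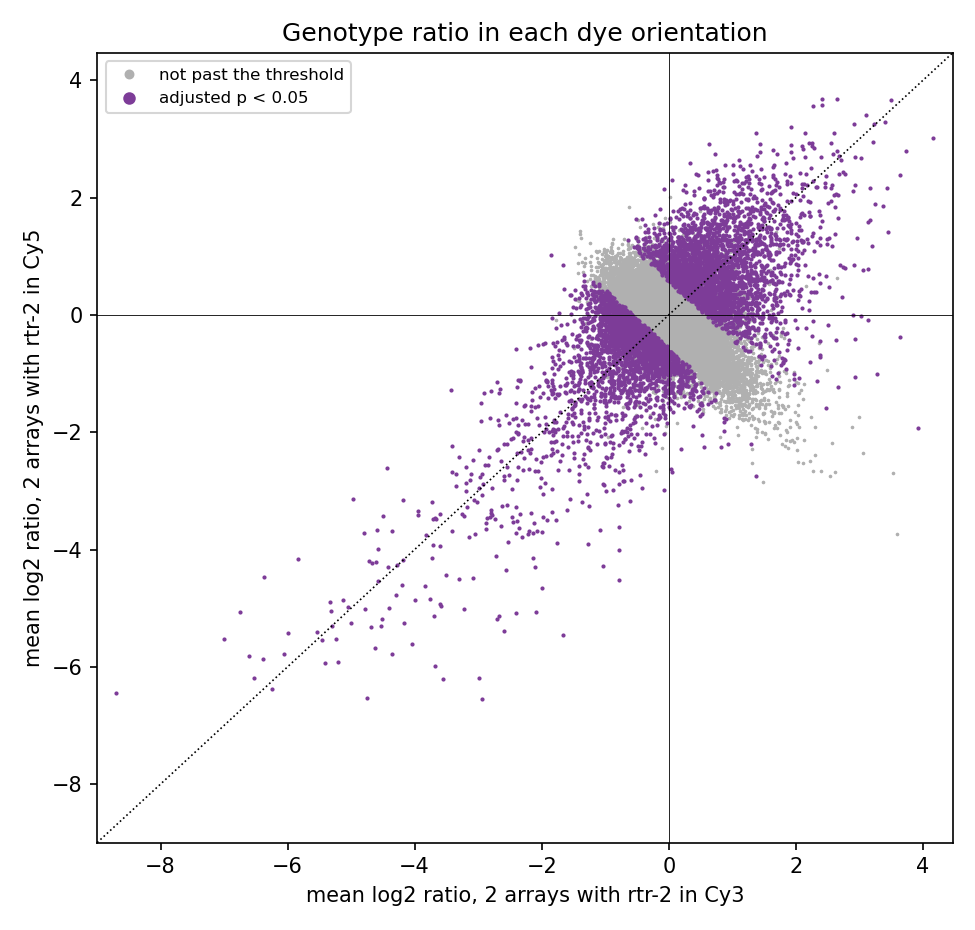
Mean log2 ratio of rtr-2 over wild type on the 2 arrays with rtr-2 in Cy3 (horizontal axis) against that on the 2 arrays with rtr-2 in Cy5 (vertical axis), for each feature with values on all 4 arrays, where purple points passed an adjusted p of 0.05, grey points did not, and the dotted line marks equal ratios. Over all features the correlation was 0.249, and over the features that passed, which were selected for like ratios, it was 0.735.

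Arrays of the same dye orientation were much more alike than arrays of opposite orientation. Across features, which are not independent replicates, the former correlated at 0.825 and 0.919 and the latter at 0.143 to 0.322. The correlation between the mean ratios of both orientations fell with brightness. In 3 equal groups of features it was 0.428 in the dimmest, 0.273 in the middle and -0.009 in the brightest. In the same order 25.5%, 25.9% and 22.5% of the features changed. The brightest group thus held 1875 changed features although its orientations did not correlate. A dye difference passed the threshold for 10495 features (41.9%). Of all features with 4 values 28.2% had the same sign on all 4 arrays; as arrays of an orientation are alike, no share by chance is given. Of those that changed, which pass more readily where arrays are alike, 85.2% had the same sign in both orientations, and 4705 of the 6169 had the same sign on every array with a value. In all, 11 lists passed camera with the preset correlation, 6 higher and 5 lower, against 0 with an estimated correlation (smallest adjusted p = 0.422) and 13 in fry's directional test, which does not compare a list with other genes.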

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

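The tests that weigh explanations here were chosen after the results were seen, except the pair on the dye difference, and so was the naming of JAZ7. For each named gene and each list median, the 4 array values were examined for a single array far from the rest. This picked out 7 of 153 sets. Chance would give about 7.7 if the 4 arrays were alike in all but noise. Arrays of a dye orientation are more alike, so that number does not hold here, and a deviating array can be missed. The gap of the extreme array as a share of the range was 0.874 for AT2G20142 (2.69 on replicate 1, 3.41 to 3.51 on the others). It was 0.864 for AT5G50335, lowest on replicate 3, 0.984 for SPL3 (-1.65 on replicate 3, -1.21 on replicate 4) and 0.857 for MYC2 (1.70 on replicate 3, 0.58 to 0.74 on the others). It was 0.87 for YAB3 (-0.33 on replicate 4, -0.24 on replicate 3), 0.837 for GI (0.08 on replicate 1, 0.29 to 0.33 on the others) and 0.85 for JAZ7 (-0.04 on replicate 1, 1.66 to 1.96 on the others).

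For the fall of floral organ and tapetum genes, weighed first, dim probes and background correction are argued against as the whole cause: with no background subtraction and every signal raised to at least a level that few probes not well above background exceed, the median over all 22 tapetum members was -2.79 (quartiles -4.61 and -0.908) and that over all 17 floral organ members -1.605 (quartiles -3.205 and -0.70). Of the members well above background in both genotypes on all 4 arrays, 4 of 5 and 8 of 11 fell. The test replaced a first form, on these 16 members together (12 fell, median -1.55), and 2 forms on members bright on the average of both channels, set aside because such members can be dim in rtr-2. A smaller share of flower bud tissue of all stages stays open, because genes taken as markers of the youngest flowers moved apart. LFY stood at 0.06 ± 0.19, UFO at 0.95 ± 0.14 (lost without the dye term, adjusted p = 0.142), CAL at -1.002 ± 0.10 and AP1 at -3.04 ± 0.15, with a median of -0.47. Whether these genes are confined to that stage was not tested. An effect of rtr-2 on gene activity within buds was not tested apart from bud number and stays open.

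The rise of touch, wounding and rapid stress genes was weighed next, and its list median was 1.48. A harvest hour that moves clock genes as much as the rapid stress genes is argued against. The clock genes had a median absolute log2 change of 0.224 and an upper quartile of 0.417. Of 15 clock genes 3 rose and 0 fell, so a smaller difference in hour stays open. For dilution by the loss of bud transcripts, 46 photosynthesis, stem and reference genes had a median of -0.009 and an upper quartile of 0.20. Normalization centres most features near 0 (median -0.028 over all), so a rise common to most transcripts would not be seen. The values show that the rapid stress genes rose beyond these genes, which a rise shared by both would not give. Whether both sets are equally rare in buds was not tested, so dilution stays open. Handling that differed between the genotypes cannot be told apart from genotype, because it would act on every pool alike: 13 members were higher in rtr-2 on all 4 arrays, which are all the members with 4 values. A response to rtr-2 and a changed make-up of the apex tissue were not tested and stay open.

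The dye difference of single features was weighed last, and no biological explanation was tested for it. Green background left in dim spots is argued against as the main source of the dye differences that remain after loess. Of the brightest of 3 equal brightness groups 46.6% had a dye difference, against 30.2% of the dimmest. The median absolute dye coefficients were 0.292 and 0.214. Loess takes out a trend shared by spots of like brightness, so a background effect of that kind was not tested. The base composition of the probes is a candidate source: base counts explained 43.7% of the variance of the dye coefficient in held-out probes, and 0% of that of the genotype coefficient. The coefficient fell with the percentage of A (r = -0.505 across probes) and rose with that of C (r = 0.371). What drives the remaining variance stays open.

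As for chance, 1 of 7 sign patterns of the 4 arrays gave as many changed features as the real one. This was the real pattern itself with 6169, and the highest other gave 0. In the other patterns the real genotype difference falls at least in part into the residual, so their 0 does not measure chance. Also, 7 patterns are too few for a share under 0.05, so the question is not decided.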

How the results depend on the processing

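The count of changed features stayed within 1.5 times the 6169 reported under 11 of the 12 planned settings that keep all arrays (5348 to 8071, the latter counting probes). The exception was the fit without a dye column, with 1282 changed, 709 higher and 573 lower, all 1282 among the 6169; dye differences then enter the residual. More features were lower than higher with median centring (3400 and 3118) and in the authors' value table (3693 and 3519). With 1 array left out, 2484 to 5255 features changed, 1488 to 2979 higher and 996 to 2276 lower, on 1 residual degree of freedom. That residual is the gap between the 2 arrays of the orientation that lost no array. The count at 2-fold or more rose to 2531 with the processed signals, and the cause was not tested; it was 997 to 1831 under the other settings. A stricter reading chosen after seeing the data, the same direction on every array, kept 4705, with 2470 higher and 2235 lower. Between 9 and 14 lists passed under the other settings, but 0 with an estimated correlation. A higher correlation is argued against as the cause for the salicylic acid, abscisic acid and epidermis lists. Their estimates of -0.01, -0.073 and -0.09 lay under the preset 0.01. Their camera adjusted p still rose from 0.000951, 0.00212 and 0.0374 to 0.422. With an estimated correlation camera also takes only the residual degrees of freedom, 2 here, so a small p is hard to reach for any list. The estimates of the other lists that passed lay above the preset, from 0.025 for gibberellin to 0.488 for floral organ genes. For those lists the p at the preset is too small if the estimates hold. The share of each cause was not tested. Of 1347 values of named genes under alternatives, 1254 kept direction and side of the threshold, 86 lost the call, 33 of them without the dye column, 6 gained it and 1 changed sign: RBCS2B, at 0.08 (adjusted p = 0.674, with 0.00702 to 0.674 over its alternatives) with the processed signals; the cause was not tested. Of 634 values of genes named after their values were seen, 535 kept both, 97 lost the call and 2 gained it. Of 374 values of lists, 341 kept both, 23 lost the call and 10 gained it. Aquantile scaling leaves ratios within an array as they are and so tests little. Signal over background limits the dim genes: the 8 largest falls, ACOS5 and MS2 had no value under the strict brightness filter, where the medians of the remaining tapetum and floral organ members were -2.01 and -1.095. Testing every probe on its own gave counts but no value per gene or list.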

Other observations

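Gene families were taken from key words in the array descriptions, and both the key words and the tests were chosen after the changed genes were seen. In Fisher's exact test, two-sided, 22 of 28 families passed an adjusted p of 0.05 in some direction, but families picked from the changed genes pass more readily and the test takes genes as independent, so only counts are given. Of all 21600 genes with a locus 13.3% rose and 12.8% fell. Of 70 auxin-responsive genes, SAUR genes included, 36 rose and 4 fell, and of 98 genes described as disease resistance proteins 41 rose and 3 fell. AP2 or ERF domain factors rose in 33 of 72 cases and fell in 7, calmodulin and calcium-binding proteins rose in 63 of 221 and fell in 10, and WRKY factors rose in 23 of 60 and fell in 2. Among cell wall families the directions differed: xyloglucan endotransglucosylase/hydrolases rose in 13 of 32 cases and fell in 2, and expansins rose in 8 of 20 and fell in 2. Pectinesterases or pectate lyases fell in 24 of 74 and rose in 13, and polygalacturonases fell in 13 of 44 and rose in 3.

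Histone genes fell in 13 of 34 cases and rose in 1. Lipid transfer proteins split, with 19 of 58 higher and 20 lower, and their median changed sign between scalings. Ribosomal protein genes rose in 3 of 312 cases and fell in 54, and pentatricopeptide repeat genes rose in 1 of 344 and fell in 40, or 11.6%, a share near that of all genes. Apart from lipid transfer proteins, the median of each family named here kept its sign with no background subtraction, the processed signals, median centring and the authors' value table. Families share members with the fixed lists, so these counts are not independent of them.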
